A study of Homo sapiens with 4 samples.

How the data were processed

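Human MHCC-97L cells, an established line of hepatocellular carcinoma, were grown as tumours in mice, and RNA of 4 tumours was sequenced. Mice received vehicle (5% dextrose with 15% DMSO) or PIM447, an inhibitor of the 3 PIM serine/threonine kinases, at 60 mg/kg by oral gavage 3 times a week for 2 weeks. Vehicle tumours carry the replicate numbers 1 and 5 and PIM447 tumours the numbers 7 and 8 in the labels, which give no batch and no pairing. Per the labels' protocols, libraries were made with a stranded mRNA kit and adapters with molecular identifiers from 1 µg of RNA with a mean RIN of 8.75, and were sequenced as paired reads of 151 bp. Whether the identifiers were used to collapse reads is not given in the sources used here.

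The deposited tables hold TPM, the relative transcript abundance that RSEM reports, per gene, 1 table per tumour, with 60725 entries in the same order and values to 2 decimals. The submitters' processing notes name bcl2fastq, STAR 2.5.2 and RSEM 1.2.31 and the genome build GRCh38, without roles or order. The annotation release, the use of strand and any removal of mouse reads are not given in the sources used here. Each table sums to 1000000 TPM, so the depth of each tumour is unknown, and no interval or floor that needs counts was computed. TPM is a share of the total: a rise of some transcripts lowers the values of all others, and RSEM divides reads among near-identical copies by estimation. A symbol listed more than once was kept as separate entries, and lists took the entry with the highest mean.

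The test fixed before the data were examined assumed counts, with a stated fallback for TPM, and the fallback was used. Values were transformed to log2(TPM + 1), genes with a mean of at least 1 TPM were kept, and PIM447 was compared with vehicle by limma 3.58.1 in R 4.3.3, with a trend in the variance prior and no covariates. The 4 tumours leave 2 residual degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 14301 genes, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. An exact permutation test of 2 against 2 tumours cannot give a two-sided p below 0.333.

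Before the data were examined, 42 gene lists were fixed, 32 of functions and 10 of host cell types. Lists with at least 5 tested members were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes, and adjusted over the 35 lists tested. The same lists were also tested with an estimated correlation and with fry. Named genes were fixed by rule: the 3 PIM genes, up to 12 genes in each direction, and from each list up to 4 members with the smallest p. The 12 were the genes with the largest change among those past the threshold, filled by the smallest p where fewer passed, with both tumours of one group above both of the other and clone names left out. The level that the rule set on a count scale became a mean log2(TPM + 1) of at least 1. Members of lists that did not pass the set test are given mostly as counts. Genes named outside the rule are said to be so. Coordinates and gene types come from GENCODE release 29 on GRCh38, which may differ from the annotation behind the tables; 88.9% of the tested genes had a type there.

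The gene test was tested on simulated data for the comparison of PIM447 with vehicle, with the 14301 genes at their measured levels. With variances drawn from the fitted prior, 45 of 100 genes changed 2-fold and 84 of 100 changed 4-fold were called, and 4 of 133 calls were unchanged genes. An earlier simulation with each gene's posterior variance called 79 and 95 of 100, and 21 of 195 calls were unchanged genes, or 10.8% against the nominal 5%; the drawn variances were adopted after that outcome, and the test itself was not altered. In a simulation of 35 lists of 20 independent genes, camera found the 1 lowered list and called 0 of the others. It did not cover genes that vary together. The gene simulations drew noise on the log2 scale and not as read counts. Their shares of unchanged genes therefore do not carry over to genes listed at 0 in both tumours of a group. Each gene simulation also held 100 genes of each size of change at once, while the data gave 9 calls. The Benjamini-Hochberg threshold is stricter when fewer genes differ. The shares of changed genes called may therefore be too high for these data.

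Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, leaving out each tumour in turn, a threshold of 1.5-fold, the other list tests and lists without host markers. Others were added after seeing the data: median-of-ratios scaling, rescaling without the mitochondrial genome, 2 stricter or different filters, protein-coding genes only, and 2 other variance priors. Gene counts under several of these, and under other splits of the tumours, had been looked at before the added alternatives were written down.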

Results

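Expression was measured by RNA-seq in 4 xenograft tumours of the human hepatocellular carcinoma line MHCC-97L, 2 from mice given vehicle and 2 from mice given PIM447, an inhibitor of the PIM kinases. The comparison asks which transcripts differ in tumours after PIM447. Values above 0 TPM were listed for 22071 and 21417 entries in the vehicle tumours 1 and 5 and for 22075 and 22124 in the PIM447 tumours 7 and 8. Depth was unknown because TPM keeps no counts. On log2(TPM + 1), Pearson's r across genes, which are not independent replicates, was 0.976 within each group and 0.970 to 0.975 between groups. The groups thus differed little more than replicates did. In the first principal component of the 500 most variable genes, with 40.8% of the variance, vehicle 5 lay at -24.2, vehicle 1 at -2.31, PIM447 7 at 2.30 and PIM447 8 at 24.2. The second component (31.1%) set vehicle 1 apart, at 25.6 against -12.0 to -5.01 in the other tumours. The third (28.1%) set PIM447 7 apart, at -21.8 against -3.60 to 13.6.

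The mRNAs of the kinases that PIM447 inhibits showed no difference past the test. PIM1 (chromosome 6, 37170203 to 37175426, plus strand, GRCh38) had 25.4 ± 1.27 TPM in vehicle and 21.4 ± 1.22 TPM in PIM447 tumours (SD, n = 2 each), a log2 fold change of -0.24 with a standard error of 0.12 and a limma adjusted p of 0.662. PIM2 (chromosome X, 48913182 to 48919024, minus strand) had 21.3 ± 2.47 and 18.8 ± 1.92 TPM, with a log2 fold change of -0.17 and an adjusted p of 0.784. PIM3 (chromosome 22, 49960513 to 49964080, plus strand) had 44.3 ± 5.34 and 38.0 ± 1.27 TPM, with a log2 fold change of -0.21 and an adjusted p of 0.702. The inhibitor acts on the proteins, so these values do not check the labels.

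Few single genes differed. Of 14301 genes tested, 4 were higher and 5 lower in PIM447 tumours at an adjusted p under 0.05, and none of the 9 was annotated as protein-coding, 6 of them having a gene type in the annotation used. MIR671, a microRNA precursor, was listed at 0 TPM in both vehicle tumours and at 55.61 and 56.19 TPM in the PIM447 tumours (adjusted p = 0.000149). SCARNA22, a small Cajal body RNA, was listed at 0 in both vehicle tumours and at 16.00 and 15.99 TPM after PIM447 (adjusted p = 0.00292). SNORD22, a small nucleolar RNA, had 30.94 and 31.41 TPM in vehicle and 155.57 and 223.71 TPM in PIM447 tumours, a log2 fold change of 2.54 with a standard error of 0.18 (adjusted p = 0.0154). SNORA77, another small nucleolar RNA, had 13.73 and 14.11 TPM in vehicle tumours and was listed at 0 in both PIM447 tumours (adjusted p = 0.00314).

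The pseudogene CYP4F33P had 5.89 and 8.31 TPM in vehicle tumours and was listed at 0 in both PIM447 tumours (adjusted p = 0.0282). The rest, named because they complete the count, were AL139288.1, listed at 0 in both vehicle tumours (adjusted p = 0.0119), and CTD-2012J19.2, CH17-232I21.1 and AC007326.1, listed at 0 in both PIM447 tumours (adjusted p = 0.0282 each). Altogether 8 of the 9 were at 0 in both libraries of one group. MIR671, SCARNA22, SNORA77 and SNORD22 are 118 to 126 nt long, shorter than one read of 151 bp. Without counts, how many reads their TPM values rest on is unknown. These calls therefore do not show that the RNAs were switched on or off. Without vehicle 5, SCARNA22 (adjusted p = 0.0685), SNORD22 (0.241), SNORA77 (0.0734) and CYP4F33P (0.128) lost their calls, and without vehicle 1 SNORD22 (0.215), SNORA77 (0.0542) and CYP4F33P (0.0856) did. CYP4F33P was also lost without PIM447 7 (0.123), without PIM447 8 (0.157) and with a pseudocount of 0.1 (0.105), and SNORD22 without a trend in the variance prior (0.103).

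At an unadjusted p under 0.05 there were 448 higher and 707 lower genes, where chance gives 715 in all. Both tumours of one group lay above both of the other for 39.3% of genes, against 33.3% by chance. Restricted to protein-coding genes, limma called 0 genes, with 1128 at an unadjusted p under 0.05. Without a filter on low values only MIR671 stayed past the threshold (adjusted p = 0.0484); leaving out one tumour gave 1 to 14 higher genes and 1 to 14 lower genes.

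The remaining named genes were filled in by the smallest p and did not pass the adjusted threshold. Among those with higher values, NPIPB3 had 16.2 ± 0.396 TPM in vehicle and 33.1 ± 0.375 TPM in PIM447 tumours, and NPIPB4 had 12.3 ± 1.41 and 28.9 ± 1.15 TPM (adjusted p = 0.0998 each). Both passed with a robust variance prior (adjusted p = 0.0374 and 0.0325), as did RPL39P36 (0.0152) and SNORA71 (0.0325), which were listed at 0 in both vehicle tumours. The NPIPB genes and BOLA2B, with 184 ± 8.56 and 262 ± 10.7 TPM, belong to families of near-identical copies, so their values are uncertain. AKAP13, an anchoring protein of protein kinase A, had 27.4 ± 2.30 and 43.6 ± 2.30 TPM, FAM95C 12.78 and 10.66 against 19.67 and 22.26 TPM, and RNU11, an RNA of the minor spliceosome, 34.6 ± 12.6 and 113 ± 41.7 TPM (adjusted p = 0.514 to 0.517).

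Among those with lower values, BTG1, an antiproliferative gene, had 92.9 ± 1.63 TPM in vehicle and 53.5 ± 4.21 TPM in PIM447 tumours, a log2 fold change of -0.79 with a standard error of 0.10 (adjusted p = 0.202). FSTL3, a secreted inhibitor of activins, had 105.2 ± 11.3 and 58.9 ± 1.89 TPM (adjusted p = 0.230). The metallothionein MT1X had 35.6 ± 6.78 and 15.3 ± 3.17 TPM and TMEM45A 40.4 ± 7.83 and 18.1 ± 2.90 TPM (adjusted p = 0.389 each). The long noncoding RNA PVT1 had 98.4 ± 10.9 and 61.3 ± 0.304 TPM (adjusted p = 0.434), and the pseudogene WFDC21P 5.54 ± 0.679 and 1.34 ± 0.382 TPM (adjusted p = 0.310).

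**Figure D1:**
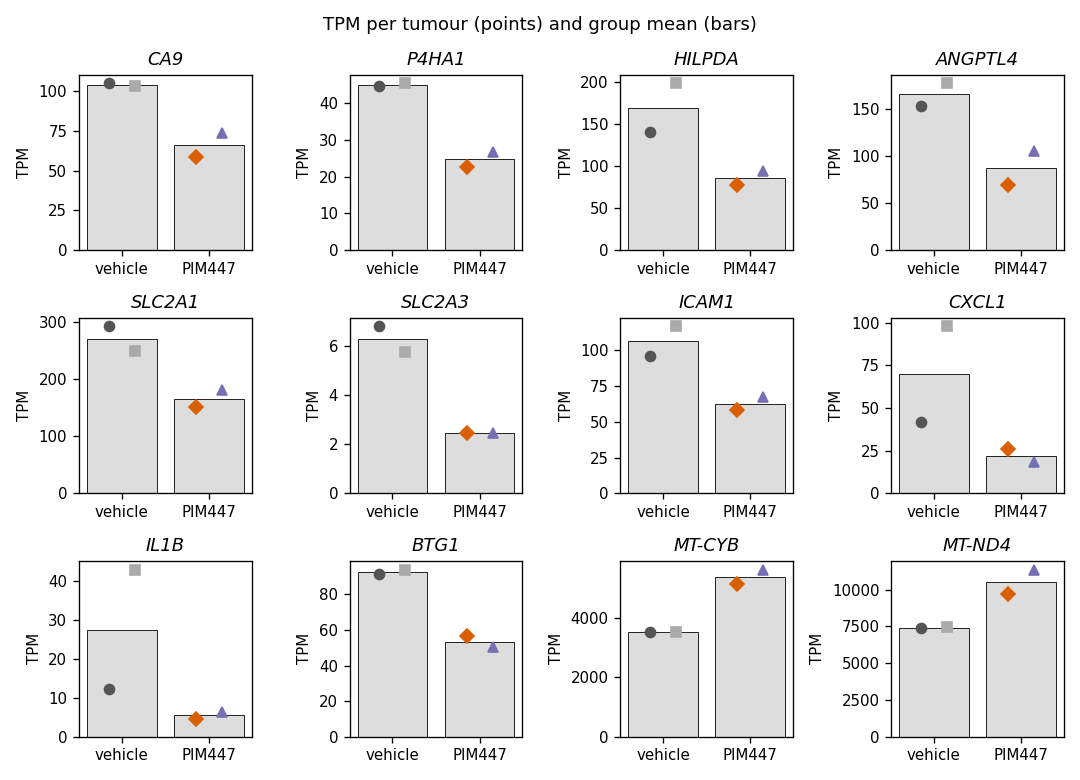
TPM (y axis, linear, from 0) of 12 genes from the named genes and gene lists in the vehicle and PIM447 groups. Bars are group means of 2 tumours. The points are vehicle 1 (circle), vehicle 5 (square), PIM447 7 (diamond) and PIM447 8 (triangle). ANGPTL4, a hypoxia list member, and IL1B, an NF-kB list member, are shown outside the naming rule. Vehicle 5 stands apart for IL1B, at 43.03 TPM against 12.12 TPM in vehicle 1.

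Gene lists showed lower hypoxia, glycolysis and NF-kB genes and higher transcripts of the mitochondrial genome in the PIM447 tumours. Of 35 lists tested, 13 passed camera with its preset correlation, 12 lower and 1 higher. With a correlation estimated for each list none of the 13 passed (adjusted p = 0.637 for each with an estimated correlation), and fry called 0 lists (lowest adjusted p = 0.125). The 2 other ways of splitting the 4 tumours into pairs gave 15 and 8 lists with the preset correlation, against 13 for treatment. The lowest adjusted p was 1.89e-12 for treatment and 5.74e-06 and 2.47e-07 in those splits, with 4 lists under 1e-06 against 0 and 1, and 1155 genes at an unadjusted p under 0.05 against 292 and 665. No member of any tested list passed the gene test over all genes.

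The hypoxia response list, made of targets of hypoxia-inducible factors, had 21 of 22 members at lower values in PIM447 tumours, with a median log2 fold change of -0.49 (camera adjusted p = 1.89e-12, and adjusted p = 0.637 with an estimated correlation). Adjusted over the list alone, 11 members were lower, against 0 over all genes. P4HA1, a collagen prolyl hydroxylase, had 45.0 ± 0.594 TPM in vehicle and 24.8 ± 2.89 TPM in PIM447 tumours (log2 fold change -0.84, standard error 0.12). HILPDA, a lipid droplet protein, had 140.75 and 199.20 against 77.24 and 94.26 TPM, the carbonic anhydrase CA9 104.0 ± 1.40 and 66.2 ± 10.6 TPM, and INSIG2 59.4 ± 10.9 and 35.5 ± 0.983 TPM.

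The glycolysis list had all 20 tested members at lower values, with a median log2 fold change of -0.35 (camera adjusted p = 4.36e-09, and adjusted p = 0.637 with an estimated correlation). Adjusted over the list alone, 7 were lower, against 0 over all genes. The glucose transporters SLC2A3 and SLC2A1 had 6.25 ± 0.750 and 271 ± 30.3 TPM in vehicle and 2.44 ± 0.0212 and 166 ± 21.6 TPM in PIM447 tumours. TPI1, triosephosphate isomerase, had 1605 ± 13.9 and 1248 ± 85.9 TPM, and PGAM1, phosphoglycerate mutase, 270.5 ± 8.20 and 212 ± 11.6 TPM. PIM447 tumour 7 lay lowest, and without it the median was -0.19.

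The list of NF-kB targets, mostly chemokines, cytokines and feedback inhibitors of the pathway, had 17 of 18 members at lower values and a median log2 fold change of -0.72 (camera adjusted p = 5.68e-12, and adjusted p = 0.637 with an estimated correlation). Adjusted over the list alone, 14 were lower, against 0 over all genes. The adhesion molecule ICAM1 had 106 ± 14.4 TPM in vehicle and 62.6 ± 6.53 TPM in PIM447 tumours. The chemokines CXCL3 and CXCL1 had 23.9 ± 9.91 and 69.9 ± 39.7 TPM in vehicle and 8.87 ± 1.65 and 22.0 ± 5.35 TPM after PIM447, and BIRC3, an inhibitor of apoptosis, 48.9 ± 20.4 and 21.3 ± 2.52 TPM. Vehicle tumour 5 had the highest values of these 4 genes, such as 97.94 TPM of CXCL1 against 41.81 TPM in vehicle tumour 1.

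The mitochondrially encoded list had all 13 members at higher values, with a median log2 fold change of 0.47 (camera adjusted p = 3.93e-11, and adjusted p = 0.637 with an estimated correlation). Adjusted over the list alone, 5 were higher, against 0 over all genes. MT-CYB, of complex III, had 3529 ± 7.89 TPM in vehicle and 5396 ± 345 TPM in PIM447 tumours, a log2 fold change of 0.61 with a standard error of 0.10. MT-ND4 had 7387.81 and 7461.59 TPM in vehicle and 9690.82 and 11379 TPM in PIM447 tumours. The mitochondrial genome took 10.4% and 9.73% of TPM in the vehicle tumours and 11.3% and 15.9% in PIM447 tumours 7 and 8. The median was 0.25 without PIM447 tumour 8 (camera adjusted p = 0.000147) and 0.72 without PIM447 tumour 7, and the list passed camera without any one of the 4 tumours. Nuclear pseudogenes can share reads with these genes.

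**Figure D2:**
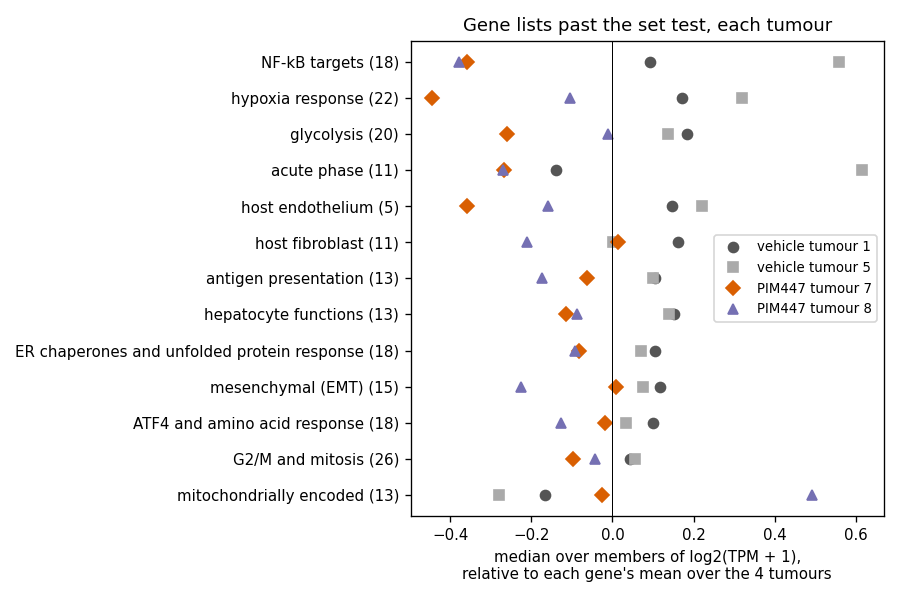
For each of the 13 lists past camera with its preset correlation (members tested in parentheses), points give the median over members of log2(TPM + 1) relative to each gene's mean over the 4 tumours (x axis, log2) in each tumour. The medians of the PIM447 against vehicle log2 fold changes run from -0.72 (NF-kB targets) to 0.47 (mitochondrially encoded). Single tumours stand apart in several lists. Vehicle 5 does in acute phase and NF-kB targets (the latter at 0.56 against 0.092 in vehicle 1), and PIM447 8 in mitochondrially encoded. In hypoxia response and glycolysis PIM447 7 lies at -0.44 and -0.26 and PIM447 8 at -0.10 and -0.011. In the mesenchymal and host fibroblast lists PIM447 8 lies at -0.23 and -0.21 and PIM447 7 at 0.0099 and 0.014.

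Lists of antigen presentation, ER chaperones and hepatocyte functions differed less. Antigen presentation had 12 of 13 members at lower values (median log2 fold change -0.26, camera adjusted p = 0.000377), with PSMB9, an immunoproteasome subunit, at 15.77 and 19.29 TPM in vehicle and 11.82 and 12.53 TPM in PIM447 tumours. ER chaperones had 17 of 18 members at lower values (median -0.19, adjusted p = 0.000754), with DNAJB9 at 25.83 and 25.94 against 19.89 and 20.32 TPM. Neither list had a member past the threshold adjusted over the list alone. Hepatocyte functions had 11 of 13 at lower values (median -0.24, adjusted p = 0.00189), and 2 passed adjusted over the list alone: SERPINA1, the antitrypsin gene, with 206 ± 3.44 and 134 ± 8.06 TPM, and the transferrin gene TF, with 172.73 and 155.91 against 98.97 and 121.43 TPM. With an estimated correlation each list had an adjusted p of 0.637.

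The ATF4 and amino acid response list had 13 of 18 members at lower values (median -0.18, camera adjusted p = 0.0105). Adjusted over the list alone, 1 passed, the serine synthesis enzyme PSPH (32.5 ± 1.39 and 20.6 ± 0.877 TPM). Acute phase had 8 of 11 members at lower values (median -0.35, adjusted p = 0.0258). In that list 1 passed, the complement gene C3 (7.25 and 12.65 against 3.01 and 1.56 TPM). Relative to gene means, its medians were -0.14 in vehicle 1, 0.62 in vehicle 5 and -0.27 in each PIM447 tumour. G2/M and mitosis had 22 of 26 members at lower values (median -0.13, adjusted p = 0.0258), with the proliferation marker MKI67 at 36.45 and 42.70 against 30.38 and 33.11 TPM. The mesenchymal list had 11 of 15 (median -0.18, adjusted p = 0.0475), with the fibronectin gene FN1 at 5949.28 and 6705.53 against 5312.43 and 4202.45 TPM. Neither G2/M nor the mesenchymal list had a member past the threshold adjusted over the list alone. Each of the 4 lists had an adjusted p of 0.637 with an estimated correlation. Each lost its call without one or more tumours: ATF4 without vehicle 1 (median -0.11, adjusted p = 0.0605) or PIM447 8 (-0.069, 0.190), and acute phase without PIM447 7 (-0.40, 0.122), PIM447 8 (-0.72, 0.0545) or vehicle 5 (0.014, 0.850). Without vehicle 1 the acute phase median was -0.75. G2/M lost it without vehicle 5 (0.246) or PIM447 7 (0.204), and the mesenchymal list without vehicle 1 (0.0608), vehicle 5 (0.246) or PIM447 8 (median -0.099, 0.680). Without PIM447 7 the mesenchymal median was -0.34. At a mean of at least 5 TPM, G2/M (0.0614), acute phase (0.129) and the mesenchymal list (0.0676) lost their calls. G2/M also did without the mitochondrial genome (median -0.076, 0.0837) and among protein-coding genes (median unchanged at -0.13, 0.0536). Acute phase also lost it with at least 1 TPM in 2 libraries (0.0812) and the mesenchymal list with no filter (0.144).

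Markers of host cells were sparse. Host endothelium had 5 tested members, all lower (median -0.30, adjusted p = 0.0271), with EGFL7 at 7.43 and 7.08 TPM in vehicle and 4.38 and 5.18 TPM in PIM447 tumours. Host fibroblast had 9 of 11 members at lower values (median -0.29, adjusted p = 0.0475), with the collagen gene COL6A2 at 243.19 and 218.06 against 205.35 and 188.25 TPM. Both had 0 members past the threshold adjusted over the list alone and an adjusted p of 0.637 with an estimated correlation. The endothelial call was lost without vehicle 5 (median -0.37, adjusted p = 0.178) or PIM447 7 (-0.42, 0.179), and without PIM447 8 the median was -0.52. The fibroblast call was lost without vehicle 1 (median -0.16, adjusted p = 0.149), vehicle 5 (-0.34, 0.0887) or PIM447 8 (-0.12, 0.729), with no filter (0.170) or at a mean of at least 5 TPM (0.189). Host keratinocyte did not pass (median 0.11, adjusted p = 0.356) except without PIM447 8 (0.43, 0.00324). Lists of host pericytes and smooth muscle, macrophages, neutrophils, B and NK lymphocytes, erythroid cells, skeletal muscle and adipocytes had 1 to 4 members at 1 TPM or more and were not tested. Of the 3 macrophage members, adjusted over the list alone, 2 were lower, CD68 (71.6 ± 4.49 and 51.9 ± 2.72 TPM) and LYZ (219.02 and 215.90 against 167.57 and 189.66 TPM), with adjusted p values over all genes of 0.540 and 0.578.

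Several other fixed lists did not pass the set test. MYC targets of ribosome biogenesis had a median log2 fold change of 0.048 (adjusted p = 0.0640). It passed under median-of-ratios scaling (median 0.086, adjusted p = 0.0339), without the mitochondrial genome (median 0.11, 0.0218), at a mean of at least 5 TPM (0.0454), among protein-coding genes (0.0362) and without PIM447 7 (0.12, 0.00857); leaving out one tumour gave medians of 0.00065 to 0.12. The BCL2 family (median -0.10), JAK-STAT feedback and STAT3 targets (-0.12), p53 targets (-0.14), translation initiation (-0.084) and G1/S and DNA replication (-0.092) had adjusted p values of 0.161 to 0.409. JAK-STAT feedback passed without vehicle 1 (0.0347) or PIM447 8 (0.0311). Heat shock (-0.12, adjusted p = 0.0709), drug metabolism and efflux (0.058), interferon response (-0.16) and MAPK feedback (-0.091) did not pass either; in the last, adjusted over the list alone, 1 member was higher, FOSL1 (45.50 and 42.18 against 59.56 and 61.42 TPM), and 2 were lower, IER3 and ETV5. Heat shock and interferon response passed with no filter on low values (0.0259 and 0.0312), heat shock without vehicle 1 (-0.15, 0.00924), and drug metabolism at a mean of at least 5 TPM (0.0347).

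Epithelial genes (median 0.030), immediate early genes (-0.061), replication-dependent histones (0.059), Wnt targets (0.021), NRF2 targets (-0.048), fatty acid synthesis (-0.069), ribosomal proteins (-0.031) and YAP targets (-0.11) had adjusted p values of 0.233 to 0.657. Ribosomal proteins passed without vehicle 1 (-0.10, 0.0221) and immediate early genes without PIM447 7 (-0.22, 0.00163). For nuclear-encoded oxidative phosphorylation the median was 0.0034 and the test pointed down (adjusted p = 0.657). For cholesterol synthesis (median -0.018, adjusted p = 0.657) and liver stem and progenitor genes (-0.025, adjusted p = 0.861) the median and mean were below 0 and the test pointed up, since the median of all genes was -0.042.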

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

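The tests under median-of-ratios scaling, rescaling without the mitochondrial genome, the filters of at least 1 TPM in 2 libraries and a mean of at least 5 TPM, protein-coding genes only and the other variance priors were chosen after seeing the data. Against 4 higher, 5 lower genes and 13 lists, a pseudocount of 0.1 gave 3 lower genes, no filter gave 1 higher and 0 lower, a mean of at least 5 TPM gave 3 lower, protein-coding genes only gave 0 and 0, and the robust prior gave 11 higher. No filter, a mean of at least 5 TPM and protein-coding genes only change which genes are tested; the cause was not tested for the others. Leaving out one tumour gave 1 to 14 higher genes, 1 to 14 lower genes and 8 to 13 lists, 8 of them without vehicle 5; the lone tumour of a group was assumed to vary like the other group. An estimated correlation and fry gave 0 lists each, and every other setting run for lists gave 10 to 14; without the mitochondrial genome its own list could not be tested. The PIM1, PIM2 and PIM3 log2 fold changes stayed below 0 and past no threshold in all settings run. With 1 tumour left out they ran from -0.29 to -0.18 for PIM1, from -0.28 to -0.053 for PIM2 and from -0.33 to -0.091 for PIM3. No paired analysis was possible because the groups share no replicate numbers. Other normalizations, filters and tools fixed before the data were examined for count tables were not run, since the values are TPM. Depth is unknown, so what it limits could not be measured.

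Directions changed, with the cause not tested, in results that had not passed, acute phase without vehicle 5 excepted. A list counts here when its median or its test turned. With no filter this held for cholesterol synthesis (-0.018), liver stem and progenitor (0.019) and Wnt targets (-0.043). Under median-of-ratios scaling it held for ribosomal proteins (0.0075), cholesterol synthesis (0.020) and liver stem and progenitor (0.012). Without the mitochondrial genome it held for ribosomal proteins (0.028), cholesterol synthesis (0.040), NRF2 targets (0.0099), nuclear-encoded oxidative phosphorylation (0.062), liver stem and progenitor (0.032) and RGS5 (0.00090). At a mean of at least 5 TPM it held for liver stem and progenitor (0.0023), Wnt targets (-0.038) and replication-dependent histones (0.0099), and by fry for cholesterol synthesis (-0.018) and liver stem and progenitor (-0.025). Leaving out one tumour turned the lists acute phase (-0.75 to 0.014), cholesterol synthesis (-0.055 to 0.048), drug metabolism and efflux (-0.040 to 0.16), epithelial (-0.042 to 0.14), fatty acid synthesis (-0.15 to -0.056), host keratinocyte (-0.21 to 0.43), immediate early (-0.22 to 0.081), liver stem and progenitor (-0.11 to 0.019), NRF2 targets (-0.075 to -0.030), nuclear-encoded oxidative phosphorylation (-0.072 to 0.037), replication-dependent histones (-0.14 to 0.19), ribosomal proteins (-0.10 to 0.048), Wnt targets (-0.13 to 0.15) and YAP targets (-0.27 to 0.051), as log2 medians. It also turned the log2 fold changes of ACAT2 (-0.035 to 0.34), ATF3 (-0.53 to 0.059), ATP2A1 (-0.58 to 0.64), CD79A (-0.30 to 0.43), CLDN7 (-0.40 to 0.14), CTGF (-0.69 to 0.28), FADS2 (-0.39 to 0.011), HBB (-0.084 to 0.45), HIST1H2BK (-0.0028 to 0.67), ITGAM (-0.14 to 0.18), KRT10 (-0.035 to 0.073), KRT14 (-0.61 to 0.88), KRT15 (-0.21 to 0.43), NEB (-0.016 to 0.31), PPARG (-0.18 to 0.0032), RGS5 (-0.18 to 0.10), RNF43 (-0.012 to 0.32), SFN (-0.0094 to 0.49), TAGLN (-0.75 to 1.15), TNNI2 (-0.34 to 0.27) and ZNRF3 (-0.13 to 0.32).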

Other observations

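The tests of dilution, of host cells, of vehicle tumour 5, of PIM447 tumour 7, of gene counts under other splits and the 3 tests of the mitochondrial transcripts were chosen after the result had been seen. The 5 genes in the next paragraph were also chosen after their values were seen, and none passed the adjusted threshold. All 5 had lower values in PIM447 tumours. Other genes looked at had higher values, such as HES1 (mean of 52.3 TPM in vehicle and 70.8 TPM in PIM447 tumours) and NUCKS1 (205 and 302 TPM). These did not pass either (limma adjusted p = 0.527 each).

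The growth factor binding protein IGFBP3 had 626.50 and 924.38 TPM in vehicle and 392.46 and 478.02 TPM in PIM447 tumours (adjusted p = 0.540), and EFNA1, an ephrin ligand, 387.86 and 516.06 against 205.64 and 263.62 TPM (adjusted p = 0.517). PTHLH, parathyroid hormone-like hormone, had 92.58 and 117.99 against 36.94 and 57.28 TPM (adjusted p = 0.517), and TGFB1 69.33 and 60.03 against 41.96 and 41.59 TPM (adjusted p = 0.514). The chemokine CXCL5 had 149.30 and 251.60 against 104.78 and 92.73 TPM (adjusted p = 0.540).

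The first pattern was the lower hypoxia, glycolysis and NF-kB lists. Against dilution by the larger mitochondrial share, the medians after rescaling without the mitochondrial genome were -0.43, -0.30 and -0.67. Against vehicle tumour 5 alone, the median nearest 0 without it was -0.34. Against PIM447 tumour 7 alone for hypoxia and NF-kB, the medians without it were -0.36 and -0.72. Glycolysis without PIM447 tumour 7, at -0.19 with a standard error over members of 0.069, fell short of the bound set for the test and stays open. Because members share the same tumours, that error leaves out the spread between tumours. The same holds for the errors of hypoxia (0.071) and NF-kB (0.17) without that tumour. Fewer host reads stay open. In sum 5 host lists, mainly fibroblast (by 73.7 TPM) and macrophage (58.3 TPM), were lower by 145 TPM. That is 0.058 of the difference of the glycolysis list, 0.16 of hypoxia and 0.26 of NF-kB, but the 5 others were higher by 110 TPM. Only 3 of 17 macrophage genes reached a mean of 1 TPM, among them LYZ (217 and 179 TPM in vehicle and PIM447) and CD68 (71.6 and 51.9 TPM). The fibroblast list had a median gene at 1.46 TPM and COL6A1 at 289 TPM. Any mouse reads count only where they align to human genes, and some of these genes may also be made by tumour cells. The ratios therefore do not measure the share of host cells. The fitted trend with length, GC content and level had an r squared of 1.33%. Its removal moved the hypoxia, glycolysis and NF-kB medians by 0.052, 0.044 and 0.046, against 0.048 for all genes, and left them at -0.44, -0.31 and -0.68. The trend as fitted thus does not account for these medians. Since its removal moved the lists about as much as all genes, it cannot decide on a bias of length or GC content, which stays open. How the tumours were grouped stays open, and a lower hypoxic state after PIM447 was not tested apart from these. Of the 3 splits of the 4 tumours, too few for a share under 0.05, 2 gave at least 13 lists (highest other 15) and 1 at least 9 genes (highest other 8). The medians were -0.49 against 0.24 and -0.099 for hypoxia, -0.35 against 0.055 and -0.14 for glycolysis and -0.72 against 0.24 and 0.30 for NF-kB. Glycolysis (camera adjusted p = 0.0308 and 0.0139) and NF-kB (0.00178 and 0.0139) also passed in both other splits with the preset correlation. Hypoxia passed in 1 of them (1.32e-05) and not in the other (0.750).

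The second pattern was the higher mitochondrial messenger RNAs. A rise of all mitochondrial RNA as large as theirs would match their median of 0.47, which had a standard error over members of 0.037. The mean log2 fold change of the 2 ribosomal RNAs was 0.054, and 2 standard errors above it, with errors taken as fully shared, lay at 0.37. Because members share the same tumours, the 0.037 leaves out the spread between tumours. With 1 tumour left out the median ran from 0.25 to 0.72, so a rise as large is not ruled out. A smaller rise of every kind also stays open, since with independent errors (0.11) that limit was 0.27, above the bound of 0.23 set for the test. PIM447 tumour 8 may account for part of the pattern: without it the median was 0.25 with a standard error over members of 0.065, also near the bound of 0.23. Still, 11 of 13 members were above 0 without it, so the size of that part cannot be told apart from the treatment. The split of vehicle 5 and PIM447 7 against vehicle 1 and PIM447 8 gave a median of -0.38 for this list (camera adjusted p = 0.00757), close in size to 0.47. For vehicle 5 and PIM447 8 against vehicle 1 and PIM447 7 the median was 0.14 (camera adjusted p = 0.00379). The list thus passed with the preset correlation in every split.

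The third pattern was higher values of MALAT1, NEAT1, NPIPB genes and splicing-related genes, chosen after they were seen; MALAT1 had 1547.75 and 1745.92 TPM in vehicle and 2398.74 and 2206.88 TPM in PIM447 tumours (adjusted p = 0.527). For this group of 10, picked by its values, a bias of length or GC content was left undecided. The same correction moved the group (median residual 0.60) no differently from all genes. A larger share of nuclear or incompletely spliced RNA stays open. The 35 other intron-retaining and splicing genes, listed before their values were seen, had a median of 0.17, between the bounds of 0.1 and 0.2 set for the test. After the same correction, which moved all genes by 0.048, their median was 0.22. Of the 35, 31 were above 0 and 8 at an unadjusted limma p under 0.05. Camera gave them an unadjusted p of 2.9e-10 with the preset correlation and an unadjusted p of 0.0183 with an estimated correlation. The latter cannot be set beside the adjusted p of 0.637 given for other lists. The lowest unadjusted camera p-values of the fixed lists with an estimated correlation were 0.0537 (ER chaperones) and 0.0639 (hepatocyte functions). Those lists were fixed before the data were examined, but the theme of the 35 came from the group picked in these same tumours. Their p-values are therefore not independent evidence for the pattern. No value under other splits or with 1 tumour left out is given for the 35. Copies of NPIPB share reads, and no biological explanation was tested.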
